A study of Homo sapiens with 6 samples.

How the data were processed

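THP-1 is a human cell line grown from a monocytic leukaemia. After a night in hormone-depleted medium, cells received either the solvent (ethanol at 0.1%, called vehicle) or 1α,25(OH)2D3, the active hormone form of vitamin D, at 100 nM (called 1,25D), for 24 h. Total RNA was copied into biotin-labelled cRNA and hybridised to Illumina bead arrays, per the labels. There were 6 arrays, 3 per group, each placed in its group by its title. The number of arrays limits the precision of every value.

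The deposited table gave 1 intensity per probe and array, on a linear scale, with no scaling between arrays and no value below 0; the program that wrote it is not given in the sources used here. It also held a deposited detection p-value per probe and array, which falls as the intensity rises. A separate table held the authors' processed values on a log2 scale. The submitters' processing notes name lumi, with no version, and its transformation and normalization are not given in the sources used here. Within each array these log2 values of the authors had the same rank order as the intensities, and their array medians ran from 7.01 to 7.03. They were used only as an alternative.

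The intensity table held 48701 probes per array. Between 16901 and 17598 of them, 34.7% to 36.1%, had a detection p under 0.05: 17215 to 17598 on the vehicle arrays and 16901 to 17055 on the 1,25D arrays. Median intensity was 85.0 to 86.1 on the vehicle arrays and 77.8 to 81.7 on the 1,25D arrays, and mean intensity 439 to 493 and 371 to 415, so every 1,25D array was dimmer than every vehicle array. Dimness thus ran with treatment and its cause was not tested. A probe was kept when its detection p was under 0.05 on at least 3 of the 6 arrays, whatever their group, which left 17451. Names came from the annotation of the array platform, with symbols updated by gene ID through a RefSeq gene table of assembly GRCh38.p14, in which 23650 probes matched. In all, 23686 probes had 1 gene symbol, 35 had several and 24980 had none; those with several or none were left out, 4508 kept probes among them. Of the 12943 kept probes with 1 symbol, the brightest on average over all 6 arrays stood for its gene, giving 11548 genes. More than 1 kept probe was present for 1172 genes. In 180 of these at least 2 probes passed the test, and in 10 of the 180 they went in opposite directions.

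Intensities were background-corrected by normexp with the background taken from the detection p-values, raised by an offset of 16, quantile-normalized and put on the log2 scale (the neqc function of limma 3.58.1 in R 4.3.3). Groups were compared with limma's lmFit and eBayes, two-sided, and p-values were adjusted over genes by Benjamini-Hochberg with a threshold of 0.05. Every adjusted p for a gene comes from this limma fit. Values are log2 fold changes of 1,25D over vehicle with their standard errors (SE), 3 arrays per group. Where a gene's probe was not above background on any of the 3 arrays of a group, its fold is a lower bound. It is the bright group's mean against the dim group's mean of, per array, the higher of the probe's own value and the lowest value among detected probes.

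Before the data were examined, 21 pathway lists and 5 lists of markers of other cell types were fixed from general knowledge of the literature, which for the receptor target genes includes earlier work on this cell line. The pathway lists were known vitamin D receptor target genes, vitamin D metabolism and receptor, antimicrobial effectors, pattern recognition, inflammatory cytokines and chemokines, NF-kappaB feedback, MHC class II antigen presentation, interferon-stimulated genes, monocyte and macrophage markers, myeloid progenitor markers, DNA replication, mitosis, cell cycle inhibitors and exit, ribosome biogenesis and MYC-linked genes, cholesterol biosynthesis and uptake, glycolysis and glucose handling, oxidative phosphorylation, lysosome, unfolded protein response and amino acid stress, coagulation and fibrinolysis, and calcium and phosphate handling. The others were T cell, B cell, erythroid and megakaryocyte, epithelial, and fibroblast markers. Lists of at least 5 tested genes were tested with limma's camera, two-sided, at its preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 21 lists; camera with an estimated correlation and fry were alternatives. Of 704 distinct pathway genes, 568 were tested.

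The rule for named genes was also fixed before the data were examined. It took the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap, always CYP24A1, VDR, CAMP and CD14, and up to 4 members of each list with the smallest adjusted p. A few further list members outside this rule are named and were chosen after their values were seen.

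The fit was tested on simulated data of 11548 genes with the spread of vehicle against 1,25D, 3 arrays each. It recovered 16% of genes changed by 0.3 on the log2 scale, 62% of those changed by 0.5 and 100% of those changed by 1 or 2, and 4.14% of its calls were false. Only 50 genes were changed at each size, and noise was drawn independently for each gene. In the data 27.6% of genes passed the threshold, so these shares do not give the recovery or the false calls there.

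The alternatives were no background correction, an offset of 50, median centring, the authors' values, no detection filter, a strict filter (detection p under 0.01 on all 6 arrays), the mean of all kept probes of a gene, all kept probes tested singly, the replicate number as a block, an intensity trend with robust spread, array quality weights, and each array left out in turn. Added after seeing the data were limma's treat test against a fold of 1.2, leaving out probes below an intensity of 20 on all arrays of a group, and a second form of the leave-out test. In the planned form the detection filter was applied to the remaining arrays, so that some named genes were no longer tested; the added form kept the probes chosen from all 6 arrays. Slide as a block was planned and not run, because the tables used here do not name slides. Figures were drawn with matplotlib 3.10.9.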

Results

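Gene expression was measured in THP-1 cells after 24 h with vehicle or with 100 nM 1,25D, 3 arrays per group, and the question, from the title of the series, is which genes respond to the hormone through its receptor, VDR. These arrays compare hormone with vehicle at 24 h alone. They cannot separate changes through VDR from others, or direct changes from later ones. Of the 48701 probes, 17215 to 17598 were detected on the vehicle arrays and 16901 to 17055 on the 1,25D arrays. Every 1,25D array was dimmer than every vehicle array, with mean intensities of 371 to 415 against 439 to 493. Correlations of normalized log2 values over genes were 0.995 to 0.997 within vehicle and within 1,25D and 0.976 to 0.981 between the groups. No 2 arrays of a group held identical values. The first principal component, with 76.8% of the variance, separated the groups. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

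Among genes above background in both groups, CAMP and CD14 rose most in 1,25D. CAMP encodes the antimicrobial peptide cathelicidin, and CD14 is the lipopolysaccharide co-receptor of monocytes. CAMP was 73.9-fold higher (log2 6.21, SE 0.15, adjusted p = 1.2e-09) and CD14 was 69.9-fold higher (log2 6.13, SE 0.11, adjusted p = 2.3e-10). CYP24A1, the enzyme that degrades 1,25D, was not above background on any vehicle array and was at least 23.4-fold higher in 1,25D (adjusted p = 2.3e-10). Of genes above background in both groups, NPTX1, a secreted pentraxin first known from neurons, fell most. It stood at 0.160 of its vehicle level (log2 -2.64, SE 0.09, adjusted p = 1.6e-08). VDR itself, the receptor, differed by less than the spread between replicates (log2 -0.08, SE 0.15, adjusted p = 0.73).

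In all, 3191 of 11548 genes (27.6%) passed the threshold, 1612 higher and 1579 lower in 1,25D. Without vehicle replicate 1 only 1001 were lower, and with array quality weights 2545. At least 2-fold, 292 genes were higher and 77 lower (207 and 193 with median centring, 186 and 33 with no background correction, 159 and 22 with the authors' values). In the main result 24 were at least 8-fold higher and 4 at least 4-fold lower, while 2079 of the changed genes moved by under 1.5-fold. All counts by fold use fitted values, also for genes not above background in a group. RHEX, among the 4, and F3, among the 77, have bounds of only 3.45-fold and 1.98-fold. The groups did not overlap in 5001 genes (43.3%, against 10% by chance for 3 against 3). The split into higher and lower depended on the scaling. Median centring in place of quantile normalization put the median of all genes at -0.22, against -0.02, and gave 621 genes higher and 3310 lower. It sets equal the medians of all 48701 probes, of which at most 36.1% were detected on an array. It therefore lines up undetected probes and leaves the dimness of the 1,25D arrays in detected ones. The cause of that dimness was not tested, so neither scaling is shown to be the right one. List directions under that setting are given relative to the median of all genes, and counts of list members are given as called.

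**Figure D1:**
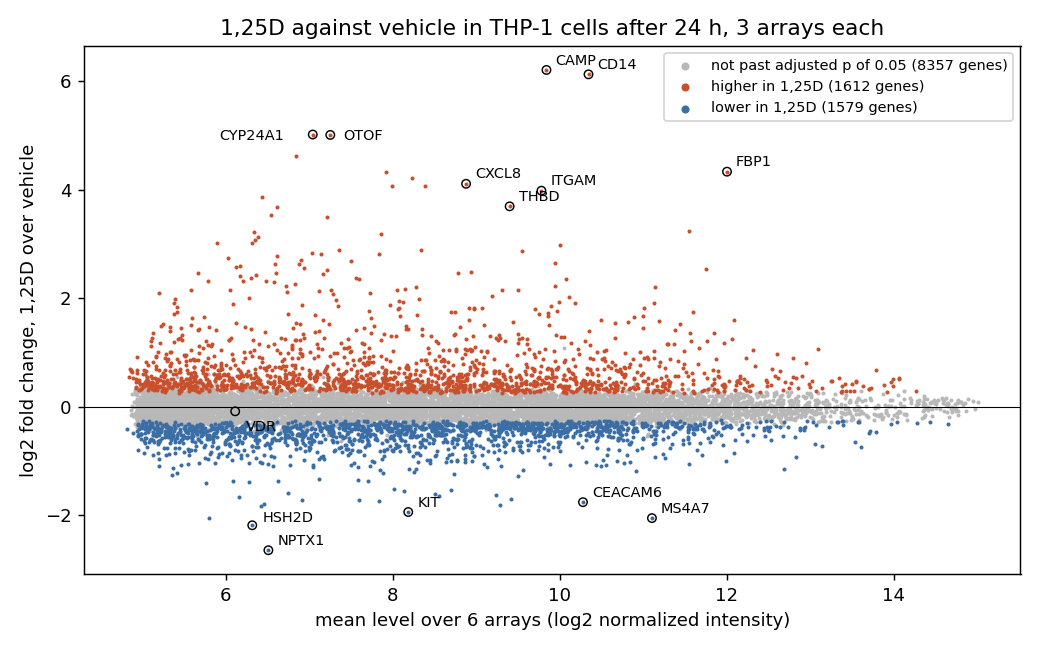
Log2 fold change of 1,25D over vehicle (vertical axis) against the mean log2 normalized intensity over 6 arrays (horizontal axis), 1 point per gene, with named genes circled. The 1612 genes higher in 1,25D are red and the 1579 lower are blue (621 and 3310 with median centring). CAMP (6.21) and CD14 (6.13) lie highest and NPTX1 (-2.64) lowest; CYP24A1 and OTOF are drawn at their fitted values, for which only bounds are given.

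Among the other largest rises, ADAMDEC1, a secreted metalloprotease of macrophages and dendritic cells, rose by 4.34 on the log2 scale (SE 0.11), FBP1, the gluconeogenic enzyme fructose-1,6-bisphosphatase, by 4.33 (SE 0.09), and GJD3, a gap junction protein, by 4.22 (SE 0.12). CXCL8, the neutrophil-attracting chemokine interleukin-8, rose by 4.11 (SE 0.13), GPER1, a membrane oestrogen receptor, by 4.07 (SE 0.09), ADAM19, a membrane metalloprotease, by 4.06 (SE 0.08) and ITGAM, the integrin CD11b of myeloid cells, by 3.98 (SE 0.11). Their adjusted p-values ran up to 9.0e-09. The probes of OTOF, a vesicle fusion protein, and TSPAN18, a tetraspanin, were not above background on any vehicle array and were at least 26.9-fold and 17.7-fold higher. A different OTOF probe was above background on at least 1 vehicle array, but on fewer than 3 of the 6 arrays. It was therefore not used, and the rise of OTOF rests on 1 probe.

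The largest falls were smaller in size than the largest rises. HSH2D, a signalling adaptor of blood cells, had a log2 fold change of -2.18 (SE 0.14, detected on 2 of 3 1,25D arrays), MS4A7, a membrane protein of the monocyte lineage, of -2.05 (SE 0.08), and KIT, the stem cell factor receptor, of -1.94 (SE 0.09). RHEX, a regulator of erythroid expansion, was not above background on any 1,25D array and was at least 3.45-fold lower. SLC51A, a subunit of a bile acid and steroid transporter (-1.83), BMP2, a bone morphogenetic protein (-1.80), and CEACAM6, a granulocyte adhesion molecule (-1.76), were lower. So were DEPTOR, an inhibitor of mTOR (-1.74), OLFML3, a secreted matrix protein (-1.72), and CXCR3, a chemokine receptor (-1.71). TARP was lower on its brightest probe (-1.81), and its 2 kept probes differed in sign. Adjusted p-values of these falls ran up to 8.3e-06.

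**Figure D2:**
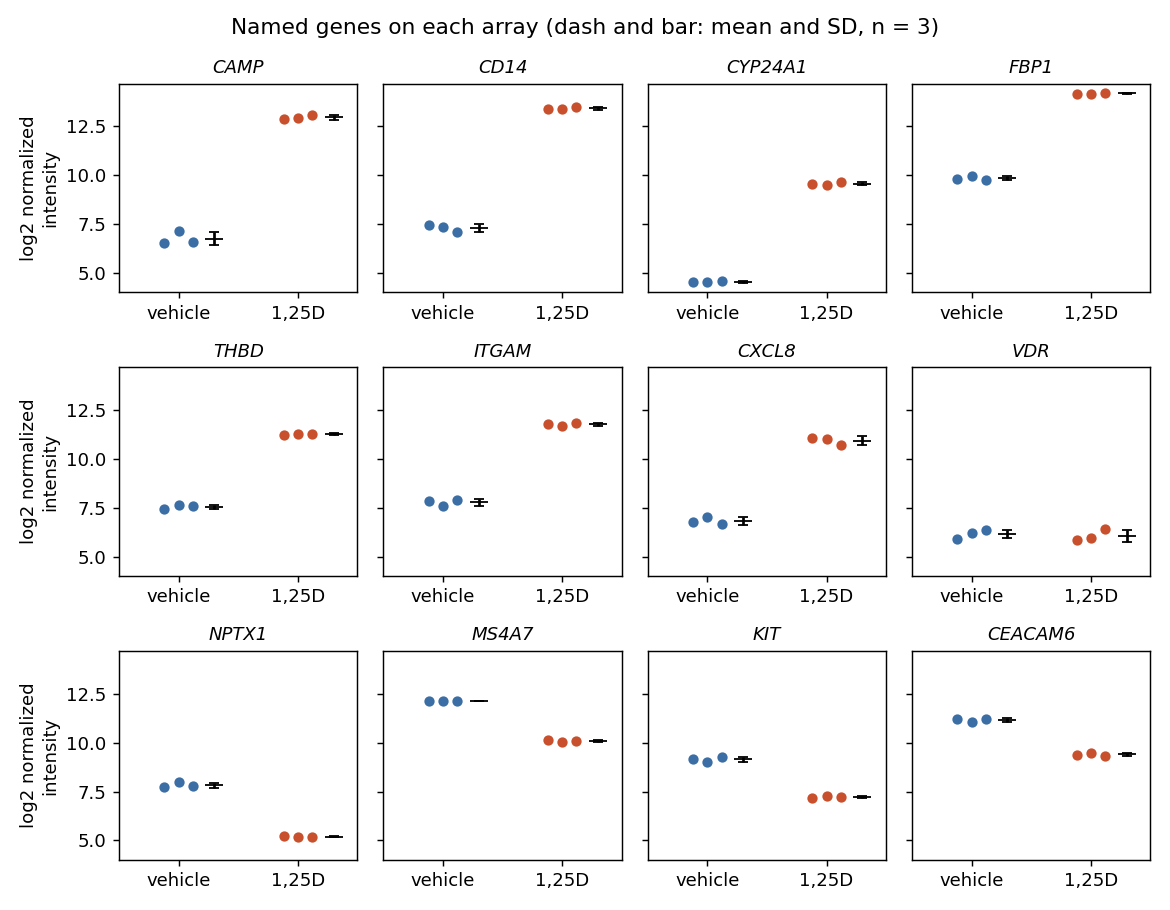
Log2 normalized intensity of 12 named genes on each array, with vehicle in blue and 1,25D in red; the dash and bar give the mean and SD (n = 3). In every gene shown except VDR the 3 values of 1,25D lie apart from the 3 of vehicle; CYP24A1 in vehicle is at background.

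Of 34 tested known vitamin D receptor target genes, 27 were higher, 2 lower and 5 not past the threshold (27 and 2 also when adjusted over the list alone, 24 and 2 with median centring). The median log2 fold change was 1.30, or 1.16 with genes at their bounds (camera adjusted p = 2.7e-22; adjusted p = 0.0137 with an estimated correlation). Besides CAMP, CD14, CYP24A1 and FBP1 they included THBD, the anticoagulant thrombomodulin, 3.70 higher (SE 0.09). The list partly comes from earlier work on this cell line, so it is not independent evidence of its direction, and 14 of its members are also in other lists. The 2 that fell were IRAK3 (-0.30) and TNFAIP3 (-0.49), both inhibitors of inflammatory signalling. In the list of vitamin D metabolism and receptor, CYP24A1 and CYP2R1, a vitamin D 25-hydroxylase (0.31, SE 0.10, adjusted p = 0.037), were higher and 9 of 11 genes did not pass. CYP2R1 lost its call in 5 of the 6 cases with 1 array left out and stood at 0.06 with median centring (adjusted p = 0.773). Adjusted over the list alone 1 was higher, and with median centring 1 was higher and 1 lower. Its median was -0.02 and its mean 0.43, and the list was not shifted (camera adjusted p = 0.457). CYP27B1, which makes 1,25D, stood at -0.07.

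Among 24 pattern recognition genes, 10 rose and 1 fell (13 and 3 adjusted over the list alone, 5 and 3 with median centring). The list was shifted up (camera adjusted p = 5.9e-05, adjusted p = 0.0996 with an estimated correlation). Its median was 0.30 in the main result, 0.15 with no background correction and 0.13 with the authors' values. With median centring it was 0.12, which was 0.35 above all genes there. TREM1, an amplifier of myeloid activation, was 2.59 higher (SE 0.11, detected on 1 of 3 vehicle arrays). LY96, the MD-2 partner of TLR4, rose by 2.15 (SE 0.13), and NOD2, a sensor of bacterial cell walls, by 1.98 (SE 0.09). TLR4 itself was at 0.04 and TLR2 at -0.36, neither past the threshold. Among 32 monocyte and macrophage markers, 14 rose and 4 fell (the same counts adjusted over the list alone, 10 and 9 with median centring), with a median of 0.11, which was -0.11 with median centring and 0.12 above the median of all genes there (camera adjusted p = 0.0034; adjusted p = 0.207 with an estimated correlation). CCR1, a chemokine receptor, was 1.82 higher (SE 0.09) beside CD14, ITGAM and THBD, and the 4 that fell were FCGR2A (-0.98), the scavenger receptors CD36 (-0.81) and MARCO (-0.51), and FPR2 (-0.45).

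The antimicrobial effectors were not shifted as a list (7 of 21 higher, 3 lower; 8 and 3 adjusted over the list alone, 4 and 5 with median centring; camera adjusted p = 0.180, or 0.0390 with median centring). Beside CAMP, the NADPH oxidase subunits NCF1 and NCF4 were 2.38 (SE 0.15) and 1.16 (SE 0.08) higher and SLPI, a protease inhibitor, 0.73 higher (SE 0.10). Whether the NCF1 probe also binds transcripts of the near-identical NCF1 pseudogenes was not checked. The 3 that fell were lysozyme (LYZ, -0.72) and the calprotectin subunits S100A8 (-0.38) and S100A9 (-0.43). Of 22 inflammatory cytokines and chemokines, 8 rose and 5 fell (8 and 6 adjusted over the list alone, 5 and 8 with median centring; camera adjusted p = 0.396). CXCL8 rose with OSM (1.13, SE 0.13, detected on 2 of 3 vehicle arrays) and CXCL1 (0.93, SE 0.11), whereas CCL2, a monocyte attractant, was lower (-0.86, SE 0.10) and TNF stood at 0.06, not past the threshold. NF-kappaB feedback genes rose in 7 of 21 cases and fell in 1 (7 and 1 adjusted over the list alone, 5 and 2 with median centring), with a median of 0.14, which was -0.10 with median centring and 0.13 above all genes there (camera adjusted p = 0.0160; adjusted p = 0.207 with an estimated correlation). BCL3 (1.44, SE 0.09), CFLAR (1.35, SE 0.13), TNFAIP2 (1.32, SE 0.11) and NFKBIA, the inhibitor of NF-kappaB (0.98, SE 0.10), were higher. This list's adjusted p was 0.0551 without vehicle replicate 2 and 0.0581 with array quality weights.

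Of 16 MHC class II antigen presentation genes 3 were higher and 6 lower (3 and 7 adjusted over the list alone, 2 and 8 with median centring; camera adjusted p = 0.396). The co-stimulator CD86 was 1.77 higher (SE 0.09) and the protease CTSS 0.65 higher (SE 0.09), while HLA-DRA (-0.76, SE 0.10) and HLA-DPA1 (-0.61, SE 0.10) were lower. Interferon-stimulated genes did not shift, with 6 of 40 higher and 4 lower (the same adjusted over the list alone, 3 and 12 with median centring), a median of -0.06 (-0.20 with median centring, 0.03 above all genes there), a mean of 0.07 and a camera test pointing up (adjusted p = 0.628). GBP2 (1.30, SE 0.09), ISG20 (0.90, SE 0.12), OAS1 (0.63, SE 0.11) and OAS2 (0.51, SE 0.09) were higher; the kept probes of OAS2 differed in sign, and its call was lost with their mean and with median centring.

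Of 44 DNA replication genes, 19 were lower, 1, POLD1, was higher and 24 did not pass the threshold (24 lower and 1 higher adjusted over the list alone, 32 and 0 with median centring), with a median of -0.26 (camera adjusted p = 4.6e-07; adjusted p = 0.0311 with an estimated correlation). They included CCNE2, cyclin E2 (-0.76, SE 0.10), FEN1, the flap nuclease (-0.65, SE 0.11), PCNA, the polymerase clamp (-0.61, SE 0.08), and MCM10, an initiation factor (-0.59, SE 0.10). Mitosis genes were not shifted: 5 of 47 were lower and 1 higher, none when adjusted over the list alone by limma (11 lower and 4 higher at an unadjusted p under 0.05; 16 lower and 0 higher over all genes with median centring), with a median of -0.01, which was -0.25 with median centring and -0.03 relative to all genes there (camera adjusted p = 0.457). MAD2L1 (-0.45, SE 0.10), CDK1 (-0.42, SE 0.11), ECT2 (-0.85, SE 0.24) and NDC80 (-0.35, SE 0.11) were lower. Leaving out each of the 6 arrays in turn, NDC80 lost its call in 4 cases, CDK1 in 3 and ECT2 in 2; ECT2 also lost it with no detection filter and was detected on 2 of 3 1,25D arrays. Among 21 cell cycle inhibitors and exit genes, 5 rose and 4 fell (the same adjusted over the list alone, 3 and 6 with median centring; camera adjusted p = 0.709). CDKN1A, which encodes p21, was 0.73 higher (SE 0.10) and GADD45B 0.63 higher (SE 0.09), while CDKN1C, which encodes p57 (-1.08, SE 0.12, detected on 1 of 3 1,25D arrays), and TOB1 (-0.65, SE 0.10) were lower; the list's median and mean differed in sign near 0.

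Ribosome biogenesis and MYC-linked genes were lower in 9 of 31 cases and higher in none by limma (9 and 0 adjusted over the list alone, 12 and 1 at an unadjusted p under 0.05, 21 and 0 with median centring; median -0.17; camera adjusted p = 0.0064; adjusted p = 0.207 with an estimated correlation). MYC itself was at -0.76 (SE 0.11), LYAR at -0.53 (SE 0.09), PUS7 at -0.51 (SE 0.09) and NOP56 at -0.50 (SE 0.09). Of 19 myeloid progenitor markers 5 were lower, among them KIT, MS4A3 (mean log2 level 12.49 in vehicle and 11.49 in 1,25D) and the repressor GFI1 (-0.79, SE 0.10), and 3 were higher, among them CD38 (0.89, SE 0.11); 6 were lower adjusted over the list alone and 8 with median centring, with 1 higher there, and the list was not shifted (camera adjusted p = 0.390). Cholesterol biosynthesis and uptake genes were lower in 7 of 30 cases and higher in none by limma (7 and 0 adjusted over the list alone, 9 and 2 at an unadjusted p under 0.05, 12 and 0 with median centring; median -0.15; camera adjusted p = 0.0156; adjusted p = 0.207 with an estimated correlation). The lower genes included ABCA1 (-1.08, SE 0.11), which exports cholesterol rather than making it, ACAT2 (-0.62, SE 0.09), TM7SF2 (-0.47, SE 0.10) and TMEM97 (-0.41, SE 0.08).

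Oxidative phosphorylation genes rose in 25 of 39 cases and fell in none by limma (31 and 0 adjusted over the list alone, 32 and 0 at an unadjusted p under 0.05, 6 and 0 with median centring). Their median was 0.36 on the log2 scale (camera adjusted p = 2.8e-10, adjusted p = 0.207 with an estimated correlation). With median centring it was 0.17, which was 0.39 above all genes there. UQCRC1 of complex III was 0.89 higher (SE 0.09), NDUFA6 and NDUFB5 of complex I 0.77 (SE 0.10) and 0.58 (SE 0.09) higher, and SDHD of complex II 0.72 higher (SE 0.12). Of 31 glycolysis and glucose handling genes, 10 rose and 3 fell (the same adjusted over the list alone, 6 and 6 with median centring), with a median of 0.08, which was -0.14 with median centring and 0.08 above all genes there (camera adjusted p = 0.0266; adjusted p = 0.277 with an estimated correlation; 0.0551 without vehicle replicate 2, 0.0700 without vehicle replicate 3 and 0.0946 with array quality weights). FBP1 works in the opposite direction to glycolysis; PFKFB4, a regulator of glycolysis, was 2.87 higher (SE 0.09), the glucose transporter SLC2A3 1.32 higher (SE 0.09) and hexokinase HK1 0.84 higher (SE 0.10). Lysosome genes rose in 11 of 40 cases and fell in 1 (12 and 1 adjusted over the list alone, 8 and 6 with median centring), with a median of 0.13, which was -0.10 with median centring and 0.13 above all genes there (camera adjusted p = 0.0014; adjusted p = 0.247 with an estimated correlation). The proteases LGMN (2.52, SE 0.08), CTSD (1.60, SE 0.08) and CTSB (1.29, SE 0.08) and the lipid-binding GM2A (1.21, SE 0.10) were higher.

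The remaining lists were not shifted. Of 30 unfolded protein response and amino acid stress genes 3 were higher and 4 lower (the same adjusted over the list alone, 2 and 8 with median centring; camera adjusted p = 0.836), with DDIT4 at 0.91 (SE 0.10), SESN2 at 0.69 (SE 0.15), HERPUD1 at 0.49 (SE 0.10) and CRELD2 at -0.40 (SE 0.08). HERPUD1 lost its call with median centring. Of 16 coagulation and fibrinolysis genes 5 were higher and 2 lower (5 and 3 adjusted over the list alone, 2 and 4 with median centring; camera adjusted p = 0.396). Beside THBD, VWF was 0.74 higher (SE 0.15, detected on 2 of 3 vehicle arrays), the transglutaminase F13A1 was lower (-1.15, SE 0.11) and F3, tissue factor, was not above background in 1,25D and at least 1.98-fold lower. Of 25 calcium and phosphate handling genes 5 were higher and 1 lower (the same adjusted over the list alone, 1 and 3 with median centring; camera adjusted p = 0.390), with ITPR2 at 1.23 (SE 0.15), ITPR1 at 0.63 (SE 0.12), KL at 0.57 (SE 0.11) and SLC20A2 at 0.41 (SE 0.09). With median centring the calls of ITPR1, KL and SLC20A2 were lost.

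Markers of other cell types were few above background. No T cell marker was tested. Of 3 B cell markers 1, CD79B, was higher and 1, FCER2, lower. Of 4 erythroid and megakaryocyte markers 1, GP9, was lower, of 2 epithelial markers 1, MUC1, was lower, and of 4 fibroblast markers 1, PDGFRB, was lower.

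**Figure D3:**
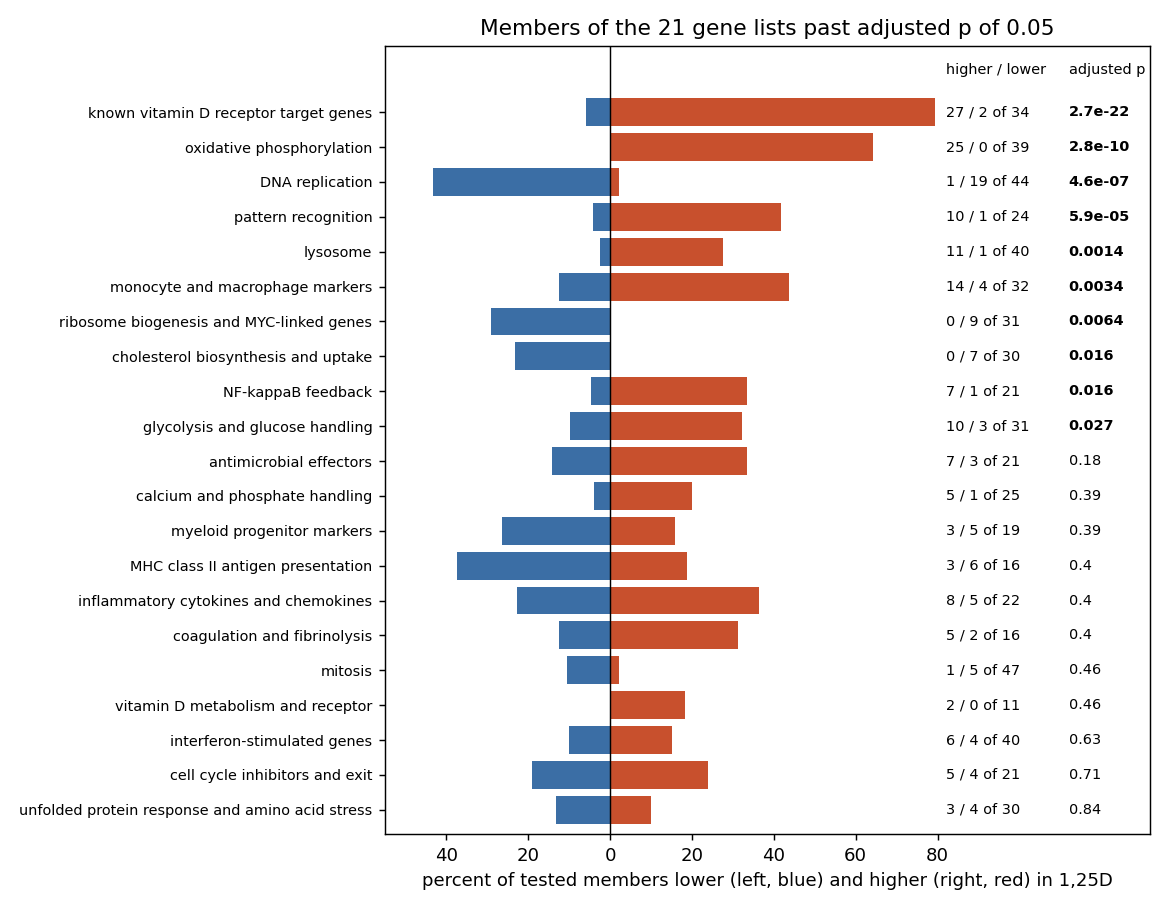
Percent of the tested members of each of 21 gene lists that were higher (red, right) or lower (blue, left) in 1,25D at an adjusted p under 0.05, with the counts and the camera adjusted p beside each bar. Receptor target genes had 27 of 34 higher, oxidative phosphorylation 25 of 39 higher and DNA replication 19 of 44 lower. With median centring 24, 6 and 32 of these members passed in the same directions, and the share for oxidative phosphorylation was then below that of monocyte and macrophage markers (10 of 32). The oxidative phosphorylation median was then 0.39 above that of all genes, against 0.37 in the main result.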

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

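Alternatives marked here as added were chosen after seeing the data: the test against a fold of 1.2, the leave-out test with a fixed set of probes, and the probes left out below. No named gene reversed its direction under any setting that gave a value. Of the 93 named genes past the threshold, 9 lost it under at least 1 of the settings that followed named genes (CYP2R1, OAS2, HERPUD1, ITPR1, KL, SLC20A2, ECT2, CDK1 and NDC80). Named genes were not followed in the test against a fold of 1.2 or with all kept probes tested singly, so losses there are not counted. Genes called both in the main result and under each other setting of the probe values, filter, design or arrays had the same direction, with 0 opposite calls. Counts and list tests not given below stayed within 1.5 times or on the same side of the threshold. With no background correction 219 genes changed at least 2-fold, 186 higher and 33 lower, and with the authors' values 181, 159 and 22; the cause was not tested. An offset of 50 gave 44 at least 2-fold lower. Median centring gave 621 higher, 3310 lower and 193 at least 2-fold lower, and an adjusted p of 0.0390 for antimicrobial effectors; the cause was not tested. Array quality weights, from 0.380 for vehicle 2 to 3.60 for vehicle 1, gave 4864 changed genes and 2545 lower, with NF-kappaB feedback at 0.0581 and glycolysis at 0.0946; the cause was not tested. The added test against a fold of 1.2 asks for a larger change and gave 991 genes, 627 higher and 364 lower. Leaving out each array in turn gave 1001 to 1329 lower genes (1001 without vehicle replicate 1), NF-kappaB feedback at 0.0057 to 0.0551 and glycolysis at 0.0124 to 0.0700. The added form gave 1036 to 1370 lower genes (1036 without vehicle replicate 1) and glycolysis at 0.0109 to 0.0619. The call for NF-kappaB was lost without vehicle replicate 2 only in the planned form, where fewer genes were tested. The glycolysis call was lost without vehicle replicate 2 in the planned form alone and without vehicle replicate 3 in both. Camera with an estimated correlation, which allows for members moving together, gave an adjusted p of 0.0996 for pattern recognition. It gave 0.207 for NF-kappaB feedback, monocyte and macrophage markers, ribosome biogenesis, cholesterol and oxidative phosphorylation. For lysosome it gave 0.247 and for glycolysis 0.277. How much of these losses comes from members moving together was not tested. Fry, which does not set a list against other genes, gave 0.0011 for vitamin D metabolism, 0.0013 for antimicrobial effectors, 0.0070 for cytokines and for progenitor markers, and 0.0015 for coagulation.

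Whether replicate numbers pair the samples could not be settled from 3 arrays per group. Correlations of same-numbered deviations were 0.08, 0.05 and 0.26, and those of other numbers ran from -0.20 to 0.12. Not every array correlated best with its own number. With the replicate block 3519 genes changed, 370 at least 2-fold, and no list call changed. The strict filter left 14 named genes with no value, CYP24A1 among them. Leaving out a vehicle array in the planned form left RHEX and F3 untested, and leaving out a 1,25D array CYP24A1, OTOF and TSPAN18, because their probes were then detected on only 2 arrays. Without the 9 probes below 20 on all vehicle arrays (added) 3189 genes changed. Signal over background limits the dim genes: 106 genes were not above background in vehicle but detected in 1,25D, and 83 the reverse. Slide as a block was not run.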

Other observations

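The groups of genes in this first paragraph, and the comparison of 9 dark probes with all others, were chosen after the values were seen. The other tests were set out before their results. Several genes raised at least 2-fold lay next to each other among the tested genes on a chromosome. On chromosome 1, LAMB3, a laminin chain (2.22), G0S2, an inhibitor of fat breakdown (3.18), HSD11B1, which regenerates cortisol (1.40), and TRAF3IP3 (1.14) formed an unbroken run. CAMP (6.21) lay beside ZNF589 (1.74), ADAM28 (2.64) beside ADAMDEC1 (4.34), CXCL8 (4.11) beside CXCL6, CARD19 (1.86) beside NINJ1 (2.53), and SHE (2.83) beside TDRD10 (2.30). ORM1 and ORM2, near-identical genes of the acute-phase protein orosomucoid, also lay side by side (2.22 and 2.09), and their probes may not be able to tell the transcripts apart.

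Of 11535 genes placed on chromosomes, 291 were at least 2-fold higher and formed 24 side-by-side pairs, against a mean of 7.29 and a highest value of 19 in 10000 random placements (one-sided permutation p = 1e-04, the smallest they can give). Members of 1 gene family could account for such pairs, yet without pairs whose symbols share their first 3 letters 20 remained, against a highest random value of 18 (permutation p = 1e-04, the smallest they can give). The 77 genes at least 2-fold lower formed 4 pairs, against a mean of 0.50, in a count with no test set out for it. The hypothesis that neighbouring genes respond together to 1,25D may therefore be worth following. Neighbours that are expressed alike under any treatment would give the same result and were not tested.

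For the rise among oxidative phosphorylation genes, 3 technical accounts were tested. With median centring the list's median was 0.17 (camera adjusted p = 4.0e-09). That was 0.39 above the median of all genes there, against 0.37 above it in the main result. These values argue against quantile normalization as the cause of the rise relative to other genes. The list's median lay at percentile 100 of 10000 random lists matched on level, whose highest median was 0.14, which argues against a rise of abundant genes in general. The 66 tested genes of cytosolic ribosomal proteins, also short and abundant, had a median of 0.0067 (95% bootstrap interval -0.04 to 0.05), far under 0.18, the value set as 50% of the list's median. By limma 0 of them were higher and 6 lower. This comparison takes ribosomal protein genes as unaffected by 1,25D, which was not tested, so it argues against a rise of short abundant mRNAs only under that assumption. The hypothesis that 1,25D raises oxidative phosphorylation genes stays open, as does an array batch running with treatment. The list's call was lost in camera with an estimated correlation (adjusted p = 0.207).

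On every vehicle array 9 probes gave intensities of 10.1 to 11.8, under the lowest value of any other probe there, 38.2, and on the 1,25D arrays 64.8 to 135. Since a transcript that is absent still gives background light, a lower transcript level in vehicle cells cannot give 11.8, the highest of these values, below the 38.2 of all other probes. An array batch running with treatment is a candidate explanation. Among 27403 probes never detected on any array, these 9 left out, 8.93% had an unadjusted p under 0.05 in limma, against 5% by chance. The 95% interval, 8.59% to 9.27%, counts probes as independent draws. Noise shared by the probes of an array can also move the share, so the interval is too narrow. The highest of the 9 other splits of the arrays, whose spread holds part of any group difference, gave 5.20%. In the real split 0 probes passed after adjustment. Faint real changes would raise the share of 8.93% too, so the size of any batch effect remains open. Slides are not named in the tables used here, so batch and treatment cannot be told apart. ADH5 was called on 1 of these probes alone and its rise is not read as a change in transcript level.

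The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 3191 changed genes and the highest other split 0 (4571 and 405 at an unadjusted p under 0.05 in limma), and 1 of the 10 splits gave as many. It gave 10 shifted lists and the highest other split 9, and 1 of the 10 gave as many. Each other split sets 2 arrays of a group and 1 of the other against the rest. Part of the difference between vehicle and 1,25D then stays in its contrast, where it can shift lists, and part enters the spread within its groups, which keeps limma's count of genes low. These splits therefore do not show what either test gives without a treatment effect.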
